A study of Gasterosteus aculeatus with 2 samples.

How the data were processed

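Nuclei had been isolated from frozen brain by gradient centrifugation and captured in droplets with a Chromium GEM-X kit that primes on polyadenylated RNA, per the labels' protocols. In such a library, each droplet carries a barcode of 16 bases, and reads with the same barcode are assigned to 1 droplet. The submitters' processing notes name Cell Ranger 9.0.1. The genome build, the annotation and the settings of the barcode filter are not given in the sources used here. The authors' filtered barcode lists and gene lists were used, 1 of each per library. They hold sequences and identifiers and no measured values, so no count model was fitted and no normalization was applied. The counts per nucleus were not analysed here. The analyses of cell classes and of expression that had been planned for such counts were therefore not run, and neither were their alternatives.

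The adult and the juvenile library were assigned to their stages from the sample titles, with 1 library per stage. The size of each library is known only as its number of retained barcodes, 54459 and 38498, which is not a depth of sequencing. The precision that these numbers give was expressed as 95% intervals of counting error. No test between stages was made. Barcodes were compared by sequence without the well suffix. Barcode pairs that differ at 1 base were counted within each library and between the libraries, the latter as background, and an exact conditional binomial test of the rates was planned. Counting by pairs that differ at 2 bases was an alternative. The pair counter was tested on a simulated list of 5000 barcodes with neighbours planted into it. The overlap was tested between 5000 simulated barcodes and a shorter simulated list. All 200 planted neighbours and all 300 planted shared sequences were recovered. The simulated sequences were random at every base and lacked the regular structure of the real barcodes, so this checks the counting alone.

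The 154 marker genes were fixed in 22 lists before the data were examined, as were the alternatives, except where stated. Symbols followed zebrafish usage, except that the mitochondrial genes were listed without the mt- prefix. All were matched whole, without regard to case. The genes named in the text are members of these lists, by a rule set in advance. Exceptions are gja1b, chosen after the values were seen, and COX1, COX2 and COX3. Lookup of LOC identifiers by gene number in the RefSeq table of fGasAcu3.hap1.1, and the COX names, were added after seeing the data. Permutation tests over markers used 10000 permutations over all lists, or 100000 within classes of markers, and the test of base composition used 10000 permutations of the library label over barcodes. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and Matplotlib 3.10.9 were used.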

Results

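Single nuclei were profiled from the brain of the three-spined stickleback (Gasterosteus aculeatus), a small teleost fish, at 2 life stages. The adult and the juvenile stage had 1 library each, and both libraries carried the same batch label. The labels do not give the number of animals behind a library. The barcodes kept for each library and the list of genes counted were analysed, whereas the counts per nucleus were not analysed here. Gene expression, the depth per nucleus and the shares of cell types are therefore not reported. With 1 library per stage, no difference between the stages could be tested against replicate error.

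The first comparison was the number of droplet barcodes retained at each stage. The adult library held 54459 barcodes and the juvenile library 38498, so the adult list was 1.41 times as long. Each barcode stands for a droplet that the authors' filter retained, and a droplet can hold no nucleus or more than 1. The ratio has no replicate check and depends on how many nuclei were loaded and on the filter, so it is a property of these libraries. Every barcode was a distinct sequence of 16 bases within its library. All barcodes carried the same well suffix, 1, in both libraries.

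The gene lists determine which brain cell types can be followed by name at both stages. Both lists held 28430 genes, and all 28430 lines were identical, so each gene of one library has its counterpart in the other. The name column repeated the identifier for every gene, and no identifier occurred on more than 1 line. Of the 28430 genes, 12512 (44.0%) had only a LOC identifier, the placeholder given to a gene without a symbol. Another 2151 (7.57%) were transfer RNA genes by name, and 13743 (48.3%) had a symbol of another kind. The last 37 genes of the list comprised 24 locus tags and 13 genes with the names of the mitochondrial respiratory chain genes, among them ND1, COX1, ATP6 and CYTB. No gene name began with the mt- prefix by which mitochondrial genes are often found.

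Of 154 marker genes fixed before the data were examined, 13 of them mitochondrial, 113 (73.4%) were present under their own symbol. A gene in the list was counted, which does not show that it was expressed. Every marker was named in 5 of the 22 lists. These were the short lists for glycinergic neurons (3 markers), oligodendrocyte precursors (5), fibroblasts and meninges (5), ependymal and ciliated cells (2), and cycling progenitors (5). The precursor list included olig2 and sox10, transcription factors of the oligodendrocyte lineage, and the progenitor list included mki67 and pcna, which mark dividing cells. At the other end, 4 of 12 radial glia markers were named, as were 3 of 6 GABAergic and 2 of 4 erythrocyte markers.

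Neuronal lists were named in unequal measure. Of 10 pan-neuronal markers, 7 were named, including elavl3, elavl4 and snap25a, while snap25b, syt1b and rbfox3b were not matched. The glutamatergic list had 4 of 5 markers, with both copies of the vesicular glutamate transporter gene slc17a6 (slc17a6a and slc17a6b). The GABAergic list had gad2, slc32a1 and slc6a1b. Neither gad1a nor gad1b, copies of the gene for a GABA-synthesising enzyme, was matched. The monoaminergic list had 10 of 11 markers, among them th for tyrosine hydroxylase, tph2 for tryptophan hydroxylase and the dopamine transporter gene slc6a3. The cholinergic list had 4 of 5, the cerebellar granule cell list 7 of 8, the Purkinje cell list 4 of 5 and the newborn neuron list 4 of 6. Of 13 neuropeptide genes, 8 were named, including oxt, gnrh2, gnrh3, npy and hcrt.

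Among glial and vascular lists, 5 of 7 oligodendrocyte markers were named, including the myelin genes mbpa and mpz. The microglia and macrophage list had 7 of 10, with csf1ra, csf1rb and p2ry12. The endothelial list had 6 of 8, the mural cell list 3 of 5 and the pituitary list 5 of 7, the last with prl for prolactin and gh1 for growth hormone. Of 13 mitochondrial protein genes, 10 were named and the other 3 were present as COX1, COX2 and COX3.

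Some markers were present without their symbol. A RefSeq gene table of the assembly fGasAcu3.hap1.1 shared 21233 (74.7%) of the 28430 identifiers. The genome build used for counting is not given in the sources used here, so the table was used for names alone and no coordinates are reported. It gave a symbol to 1745 of the 12512 LOC identifiers. Through it, 13 further markers were found, for a total of 126. In the radial glia list, gfap, the astroglial filament gene, was LOC120827734, and cyp19a1b, the brain aromatase gene, was LOC120808695. The glial glutamate transporter genes slc1a2a and slc1a2b were LOC120807747 and LOC120808655, which raised that list from 4 to 8 of 12. Another of its markers, cx43, is in the gene list as gja1b, its newer zebrafish name, and is not included in these counts. In the neuropeptide list, avp (LOC120830672), crha (LOC120816268) and agrp (LOC120809389) raised the count from 8 to 11 of 13. Both rgs5a (LOC120824189) and rgs5b (LOC120816649) completed the mural cell list, and mbpb (LOC120810966) and plp1a (LOC120818016) completed the oligodendrocyte list. The remaining additions were chatb (LOC120819616) and the complement gene c1qb (LOC120835426). These identifiers and symbols were paired by gene number in that table alone.

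**Figure D1:**
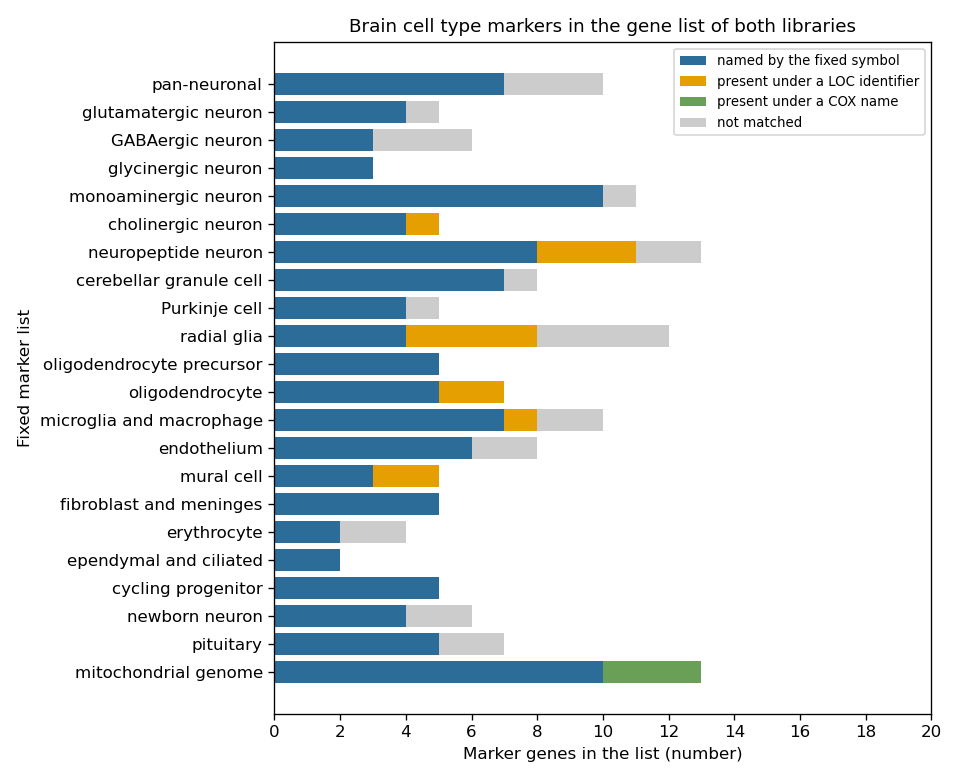
Number of marker genes (horizontal axis) in each of the 22 fixed lists (vertical axis), divided by how each gene was found in the gene list that both libraries share; no expression is plotted. Radial glia had 4 of 12 markers under their own symbol and 4 more under LOC identifiers, and the cycling progenitor list was complete. The radial glia marker cx43, listed as gja1b, is drawn as not matched.

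The barcode lists were then compared to see how many sequences the 2 libraries had in common. They shared 573 barcode sequences, with an exact Poisson 95% interval of 527 to 622. These made up 1.05% of the adult barcodes (Wilson 95% interval 0.970% to 1.14%) and 1.49% of the juvenile barcodes (1.37% to 1.61%). These intervals cover counting error only. If both libraries were independent random draws from 1 barcode list, this overlap corresponds to a list of 3652709 sequences by the Chapman capture and recapture estimate, with an interval of 3365972 to 3970654.

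No 2 barcodes within the adult library, within the juvenile library or between them differed at a single base. All 1482864111 possible adult pairs and all 741028753 juvenile pairs were compared. With 0 pairs within and between the libraries, the planned test of the rates could not be made. The structure of the barcodes, described under the other observations, rules out such pairs, so the count says nothing about split droplets. The largest difference in base composition was in the share of A at position 8, counted from the 5′ end, tied with that of G at position 9. In every barcode these bases occurred together. The share was 24.9% in the adult library (Wilson 95% interval 24.6% to 25.3%) and 24.0% in the juvenile library (23.5% to 24.4%), a difference of 0.96 percentage points. It was picked as the largest of 64 differences, and these intervals do not allow for that choice. A permutation test over all 64, chosen after the results were seen, gave p = 0.052.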

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

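Counting distinct sequences without the suffix left the adult and juvenile totals at 54459 and 38498, and comparing barcodes with the suffix left the overlap at 573. All barcodes carry the same suffix, so leaving it out or keeping it could not change these counts. The Lincoln-Petersen estimate of the barcode list was 3658922, within the interval of the Chapman estimate. Both use the same counts in nearly the same formula, so they could hardly have differed. Pairs of barcodes that differ at 2 bases numbered 17632 in the adult and 8810 in the juvenile library, where pairs that differ at 1 base numbered 0. No such single-base pair appeared without the shared barcodes, at the last base alone or at the other bases alone. Each of these settings is part of a count that was already 0, so no other outcome was possible. Leaving out the shared barcodes moved the largest base difference from 0.96 to 0.99 percentage points. Of 154 markers, 113 were named in the main setting, 103 with case as written, 113 with or without a final paralog letter, 126 with LOC lookup and 129 with LOC lookup and the COX names. The last 2 settings were chosen after seeing the data. Matching with case as written removed all 10 named mitochondrial genes, which are in capitals, and moved 1 of 22 lists by more than 1.5 times. LOC lookup moved 2 of 22 lists by more than 1.5 times, those of radial glia (from 4 to 8) and mural cells (from 3 to 5). No replicate could be left out, with 1 library per stage. The alternatives planned for cell classes and for expression were not run. The only library size known here, a number of barcodes, limits every statement to which droplets and genes were listed.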

Other observations

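In this part, the permutation tests, the Fisher test of marker names, the count of barcode forms and the overlap and reuse expected from them were chosen after the results were seen; the shared barcodes, the capture and recapture estimate, the base composition and the pairs 2 bases apart were planned. Teleost genomes retain many duplicated genes, whose copies are often named with a final a or b. In the gene list, 1025 symbol stems occurred with both letters, a name pattern that does not by itself prove a duplicate pair. The marker lists asked for both copies of 26 genes. Both copies were named for 8 of them: col1a1, csf1r, foxj1, glul, pax6, slc17a6, slc18a3 and slc6a4. A single copy was named for 14, and neither for 4, which were gad1, rgs5, slc1a2 and slc1a3. Both copies of rgs5 and slc1a2 were present under LOC identifiers. Markers with a paralog letter were named in 41 of 68 cases (60.3%) and those without in 62 of 74 (83.8%), over the 21 lists other than the mitochondrial one, with pomca counted in each of its lists (two-sided Fisher's exact test p = 0.0024; markers chosen by hand are not independent samples). An absent name does not show an absent gene. Of the 9252 LOC identifiers found in the RefSeq table, 7706 (83.3%) are protein-coding there and 929 (10.0%) are long noncoding RNAs, and 3260 were not found in it.

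Radial glia, the main astroglia of the fish brain, had the list with the lowest share of markers named (4 of 12). The names were shuffled over the 142 entries of the 21 lists (141 distinct markers, since pomca stands in both the neuropeptide and the pituitary list). A list as extreme arose with a permutation p = 0.019, so a chance spread of independent entries alone is an unlikely account of the lists as fixed. Shuffling within markers with and without a paralog letter gave a permutation p = 0.013 for radial glia alone. That p does not allow for the choice of the lowest list, so it cannot decide whether the letters account for the low share. Both shuffles treat entries as independent. Both copies of slc1a2 and of slc1a3 are among the unnamed radial glia markers, so either p may be too small. However, cx43 in the fixed list is an older symbol, and the gene is listed as gja1b, its current zebrafish name. With cx43 counted as named, the share went from 4 of 12 to 5 of 12 (41.7%), still below the next lists (GABAergic, 3 of 6, and erythrocyte, 2 of 4), and the permutation p went from 0.019 to 0.099. This correction was made in the lowest list alone, and unmatched markers of the other lists, such as galn and pvalb7, were not searched for under other names, so the p could only rise. Whether the choice of symbols accounts for the low share against the other lists therefore stays open. Of the 8 unnamed radial glia markers, 4 had only a LOC identifier by the RefSeq table, so no other symbol would have matched them. The rank also depended on the setting. Under LOC lookup, which was added after seeing the data, radial glia had 8 of 12 markers. This was no longer the lowest share, since GABAergic (3 of 6) and erythrocyte (2 of 4) markers stayed as they were. No biological explanation was tested, since the pattern concerns names. In practice, gfap, cyp19a1b and both copies of slc1a2 can be found only by LOC identifier in these libraries.

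The barcodes had a regular structure. In all 92384 distinct barcodes, the base at position 8 fixed the base at position 9, with 4 pairs of bases in use. The first 8 bases took 3838 forms and the last 8 took 3839, and any pair of forms differed at 2 or more bases. A pair of barcodes 1 base apart is thus ruled out by the list itself, and a count of 0 says nothing about droplets split over neighbouring barcodes. Pairs 2 bases apart were as frequent within as between libraries, with a rate ratio of 0.995 (95% interval 0.976 to 1.01, exact conditional binomial test p = 0.63) in the adult and 0.995 (0.971 to 1.02, p = 0.70, same exact test) in the juvenile library. These tests compare the libraries, not the stages, and treat pairs as independent. Joining every first form with every last form that the pairing rule allows gives 3683521 sequences, against 3652709 from the overlap.

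Random draws from those 3683521 sequences would share 569 barcodes, and 573 were shared, as chance overlap alone could give. The interval allows an excess of at most 52.7 barcodes, so carry-over between the libraries cannot account for most of the shared barcodes. A smaller share of them from carry-over stays open. Only retained barcodes were compared, so the overlap sets no limit on reads carried over onto barcodes that the filter removed. Barcodes were spread over the forms about as evenly as random draws, with a variance-to-mean ratio of 0.967 and 1.01 for first and last forms in the adult library and 1.03 and 1.02 in the juvenile library. The difference in base composition at position 8 (0.96 percentage points) was the largest of 64 compared, of which those at positions 8 and 9 are duplicates of each other, and had a permutation p = 0.052 over all of them, close to the threshold. Random draws from 1 list are therefore not excluded as its cause.

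If droplets drew barcodes at random from the same 3683521 sequences, about 407 further droplets of the adult library (0.747% of its barcodes) and 203 of the juvenile library (0.526%) would carry a barcode already in use. This calculation concerns barcodes alone and not droplets with several nuclei, which were not examined here.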
